A study of Mus musculus with 6 samples.

How the data were processed

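Decapsulated testes of 3 wild-type and 3 Nsun7-/- mice were used for total RNA, per the labels' protocols. The same protocols state depletion of ribosomal and globin RNA (Ribo-Zero Plus) and libraries made with the NEBNext Ultra II RNA kit, with no statement that the kit or the counting kept strand. Reads were quantified with kallisto 0.50.1 against mm39, per the submitters' processing notes. The annotation release, the strand setting and the rule that joined transcripts to gene symbols are not given in the sources used here.

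The authors deposited 3 kinds of values. The per-sample tables hold estimated counts, effective lengths in bases and TPM (transcript abundance scaled to a fixed total) for 126126 transcripts, per the file headers. A gene table deposited for the whole series holds estimated counts for 34144 gene symbols as whole numbers, and a second deposited table holds TPM for the same symbols. The deposited gene counts lay within 1 count of the sums of the transcript estimates for 96.6% to 96.8% of 31605 genes that could be matched, so the gene table was taken as kallisto's estimated counts summed and rounded. They are not corrected for depth. TPM sets each library to the same total, and Rmrp alone took between 11.4% and 33.3% of that total, so TPM of every other gene moves with the share of this one RNA. The row Ccnb1ip1 took between 0.219% and 1.2% of the counts, with 99.57% or more of them on 1 transcript of 444 bases, and overlaps the RNase P RNA gene Rpph1 in GENCODE M21. Its counts are therefore not read as Ccnb1ip1 expression. No column of another sample was present (0 found).

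Gene places came from GENCODE M21, which annotates GRCm38. Because the authors' build is mm39, no coordinates are printed, and only chromosome names, gene order and overlaps between annotated genes were used. Of the gene rows 92.5% had a place, as had 94.8% of the tested genes, and 93.6% of the transcripts matched a gene.

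Gene counts and transcript estimates, the latter rounded to whole numbers, were tested in R 4.3.3 with edgeR 4.0.16. The steps were TMM normalization, filterByExpr by genotype (minimum count 10, minimum total 15), dispersion estimation, and the robust quasi-likelihood test of knockout against wild type with genotype as the sole term, with a Benjamini-Hochberg adjusted p threshold of 0.05 and no fold minimum. Of 30388 gene rows with a count 21002 were tested, and of 103877 transcripts with a count 58773. SEs are the log2 fold change divided by the square root of the test's F value. Positive log2 fold changes mean higher in the knockout. Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over 34 lists (21 pathway lists and 13 marker lists, 538 entries of which 514 were tested), and beside it with an estimated correlation and with fry. The list named for the fibrous sheath, the other lists, the tests and the rule for named genes were all chosen before the data were examined. Results beyond that choice are named as such where they appear.

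The genes named in the text are Nsun7, the 12 largest rises and 12 largest falls, and the 2 members of smallest p from each list, whether or not they passed. A rise or fall had to pass the adjusted threshold, show no overlap between the genotypes and have a mean CPM of at least 1, and predicted or clone names were left out. For a gene with no count in any library of a genotype the fold is a lower bound against 3 counts per library, which covers counting error only. By that rule Afm is the one named gene without a wild-type count.

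Depth ran from 23480448 to 28558865 counts per library, and the biological coefficient of variation over genes was 14.9%. The tests were checked on simulated counts with the real means and library sizes, and with 50 changed genes or transcripts of each size. The simulation used the trended dispersion after a version with a dispersion for each gene had given more false calls, and both are given. With the trended dispersion the gene test recovered 28% of changes of 0.585 on the log2 scale, 88% of changes of 1 and 100% of changes of 2 and 3, and 4.82% of its 166 calls were false. With a dispersion for each gene it recovered 42%, 86%, 100% and 100%, and 6.82% of 176 calls were false. The transcript test, run on 58773 transcripts, recovered 2%, 12%, 56% and 84% at the same sizes with 6.1% false calls; with a dispersion for each transcript it recovered 0%, 6%, 44% and 56%, and 15.9% were false. In simulated data over 34 lists 0 unchanged lists were called, and a list shifted by 0.6 was recovered. Genes were drawn independently there, so this check cannot show how often lists of correlated genes are called falsely. For the lists called in the real data the estimated correlations were 0.304 (ribosomal), 0.609 (respiratory chain), 0.561 (Leydig) and 0.405 (peritubular).

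The alternatives fixed at the outset were RLE and upper quartile scaling, no filter, a filter at a mean CPM of 1, leaving out each library, the replicate number as a block, DESeq2 1.42.0, voom with sample weights, gene sums of the transcript estimates, limma-trend on log2 TPM with a pseudocount of 1 or 0.1 (mean TPM of at least 0.5), removal of mitochondrial, rRNA and globin genes, a fold minimum of 1 on the log2 scale, the estimated correlation and fry. Added after the data were seen were the removal of a length trend in each library, fits without Rmrp, Ccnb1ip1 and Lars2, fits without wild-type mouse 1 and knockout mouse 3, and TPM values centred in each library. Positions of called genes were compared with 10000 random draws of as many tested genes in Python 3.11.15 with scipy 1.17.1. This permutation test gave a p under 0.05 in 8 of 100 simulated random sets, and p = 0.0001, the smallest it can give, in a simulated clustered set. A bound for 1 position test was tightened, 1 position test that set the called genes against random draws alone was dropped once other splits of the libraries had shown that neighbouring genes vary together, and the verdict of the test without knockout mouse 1 was rewritten, all after their values were known.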

Results

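RNA was measured in the testes of 6 mice labelled C57Bl/6J and aged 3 months, 3 wild type and 3 carrying the Nsun7-/- genotype. Nsun7 belongs to the NOL1/NOP2/SUN family of putative RNA methyltransferases. The series title names it as an RNA-binding protein that destabilizes transcripts of elongated spermatids and that the placing of the longitudinal columns of the sperm tail depends on. The comparison asked which transcripts of the whole testis differ when Nsun7 is disrupted. Each library came from 1 mouse. The gene tables held 23480448, 26102343 and 25886886 estimated counts in wild-type mice 1, 2 and 3, and 25014898, 26750271 and 28558865 in knockout mice 1, 2 and 3. A single row, Rmrp (the RNA of RNase MRP), took between 1.55% and 4.85% of the counts in the wild-type libraries and between 0.985% and 1.76% in the knockout libraries. The estimated mean fragment length was 154.2, 167.7 and 175.1 bases in wild-type mice 1, 2 and 3, and 175.7, 178.5 and 175.5 bases in knockout mice 1, 2 and 3. The first principal component of log2 CPM held 35.5% of the variance, with wild-type mouse 1 at one end (-38.3) and knockout mouse 3 at the other (49.2).

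Nsun7 transcripts were lower in the knockout testes but were not lost. Normalized expression in CPM (TMM-scaled counts divided by library size, the usual scale of edgeR) was 36.5 ± 0.762 (SD, n = 3) in wild type and 20.3 ± 4.19 (SD, n = 3) in the knockout, which is 55.7% of the wild-type level. Single knockout libraries kept between 48.8% and 68.9% of the wild-type mean, and no knockout library overlapped a wild-type one in CPM. The log2 fold change was -0.84 (SE 0.15, edgeR quasi-likelihood test, adjusted p = 0.016). A two-sided exact permutation test on the CPM values gave p = 0.1, the smallest p that 3 against 3 libraries allow. The labels do not describe the allele, so which part of the mRNA remained is not known from this value. All 4 annotated Nsun7 transcripts were tested one by one. The most abundant, of 3632 bases, held 682 ± 41.5 estimated counts in wild type and 411 ± 131 in the knockout (SD, n = 3), with a log2 fold change of -0.92 and an adjusted p of 0.326 among all transcripts. The transcripts of 2775 and 2345 bases were at -1.64 (adjusted p = 0.837) and -2.01 (adjusted p = 0.932), while that of 2289 bases was not lower, with 91.4 ± 27 counts in wild type and 111 ± 27.3 in the knockout (0.09, adjusted p = 0.976). Leaving out any wild-type mouse or knockout mouse 2 raised the adjusted p of Nsun7 to between 0.0556 and 0.093, with log2 fold changes from -0.87 to -0.76 in those fits. On log2 TPM with a pseudocount of 1 and 0.1 it was at -0.46 (adjusted p = 0.406) and -0.50 (0.407), and on centred TPM at -0.75 (0.118), not called in any of these. In deposited TPM the genotypes overlapped, with knockout mouse 3 at 12.7 and wild-type mouse 1 at 10.3.

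**Figure D1:**
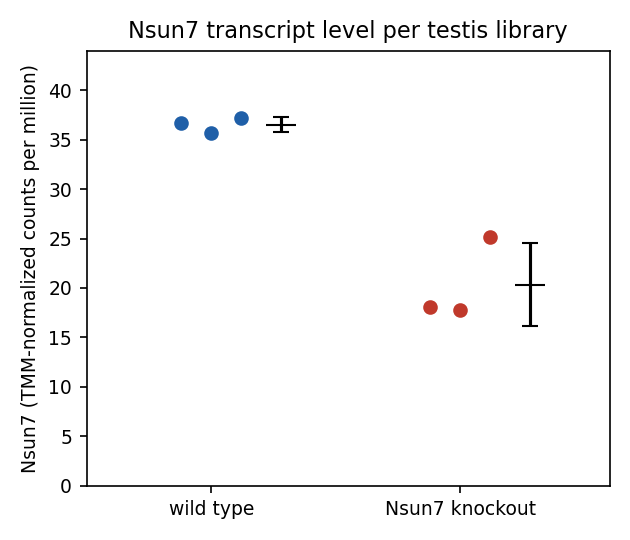
TMM-normalized Nsun7 CPM (y axis) in each testis library, by genotype (x axis). Points are mice, and the line and bars beside them are the mean and SD of 3 mice. The wild-type mean is 36.5 and the knockout mean 20.3, and knockout mouse 3 lies highest among the knockouts.

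Few genes differed between the genotypes, and many of those that did differed by several fold. Of 21002 genes tested with edgeR's quasi-likelihood test, 119 passed a Benjamini-Hochberg adjusted p of 0.05, 49 higher and 70 lower in the knockout, and 80 of them changed by at least 1 on the log2 scale. The values of the 2 genotypes did not overlap for any of the 119, nor for 14.3% of all tested genes, where chance gives 10%. The called genes were among 1763 with an unadjusted p under 0.05, and DESeq2 called 203 genes. Without wild-type mouse 1 the count was 67, and it was 78 without wild-type mouse 2 and 78 without wild-type mouse 3. Other settings gave 331 (mouse number as a block), 286 (voom), 180 (no low-count filter), 57 (centred TPM), and 52 and 48 on log2 TPM, where 33 and 30 of the calls were higher and 19 and 18 lower, so that most calls were higher rather than lower.

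The named rises included genes that were nearly silent in wild-type testis. Afm, which encodes the vitamin E-binding plasma protein afamin, had no count in any wild-type library and 2.49 ± 0.456 CPM (SD, n = 3) in the knockout, at least 20.3-fold higher when 3 counts are allowed per wild-type library. Antxr2, a cell surface receptor for anthrax toxin and collagen VI, rose from 4.45 ± 0.167 to 88.9 ± 15.4 CPM (log2 fold change 4.32, SE 0.16, adjusted p = 3.31e-09). The zinc finger gene Zfp951 rose by 2.35 on the log2 scale (SE 0.24, adjusted p = 0.000125). Stat2, a transducer of type I interferon signals, rose from 14.4 ± 1.23 to 45.5 ± 3.49 CPM (log2 fold change 1.66, SE 0.13). Shroom3, an actin-binding protein of epithelial cells, rose by 0.98 (SE 0.12) to 166 ± 16.5 CPM. Hsd3b1, a steroidogenic enzyme of Leydig cells, rose from 27.7 ± 5.46 to 62.2 ± 11.2 CPM (log2 fold change 1.17, SE 0.17, adjusted p = 0.00345). The other 6 named rises were Tmem150c (1.65), Shisa6 (1.32), the olfactory receptor Olfr161 (1.23), the steroid 21-hydroxylase Cyp21a1 (1.10), the leukocyte plastin Lcp1 (0.97) and Pm20d1 (0.91), all as log2 fold changes with adjusted p between 0.0226 and 0.0391. Each of these 6 lost its call when at least 1 library was left out, with a highest adjusted p of 0.218, for Pm20d1 without wild-type mouse 2, and none of the 6 was called on log2 TPM or centred TPM. For Tmem150c this happened without wild-type mouse 2 (0.0694), wild-type mouse 3 (0.0695), knockout mouse 2 (0.0612) or knockout mouse 3 (0.0532). Lcp1 lost it without any wild-type mouse or knockout mouse 2, Shisa6 without any mouse but knockout mouse 2, Pm20d1 without any mouse but knockout mouse 3, and Olfr161 and Cyp21a1 without any mouse but knockout mouse 1. The deposited counts are not stated to use strand, so reads from Afm, Tmem150c, Shisa6, Cyp21a1, Shroom3 and Lcp1 cannot be told from those of the genes that overlap them on the other strand. Antxr2 and Shroom3 overlap another annotated gene on the same strand. Cyp21a1, Hsd3b1, Olfr161 and Zfp951 also have close relatives with which reads may have been shared.

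The 12 named falls kept their call whichever single library was left out, with a highest adjusted p of 0.0302, but 5 of them lost it in other settings. Ttc22 fell from 9.9 ± 3.75 to 0.341 ± 0.153 CPM (log2 fold change -4.81, SE 0.38, n = 3 per genotype). Klb, which encodes the endocrine FGF co-receptor beta-klotho, fell from 18.8 ± 0.88 to 0.683 ± 0.352 CPM (log2 fold change -4.78, SE 0.25). Apoc2, the apolipoprotein that activates lipoprotein lipase, fell by 4.57 on the log2 scale (SE 0.39). The oxidoreductase gene Pyroxd2 fell from 21.6 ± 7.9 to 1.88 ± 0.285 CPM (log2 fold change -3.53, SE 0.26). Hal, the histidine ammonia-lyase, fell by 3.33 (SE 0.25). The transcription factor Sox14 had a log2 fold change of -3.25 (SE 0.37) and Spp1, which encodes the secreted phosphoprotein osteopontin, of -2.95 (SE 0.25). Lrrc66 (-2.73), the neural adhesion molecule Cntn1 (-2.46), Lgi2 (-2.26), the vomeronasal receptor Vmn1r181 (-1.65) and the hemidesmosomal collagen Col17a1 (-1.62) completed the list, all as log2 fold changes with adjusted p between 0.000301 and 0.00184. Apoc2, Spp1 and Lgi2 share their locus with another annotated gene on the same strand, and Pyroxd2 and Lgi2 with one on the other strand. On log2 TPM with either pseudocount Lrrc66, Cntn1, Vmn1r181 and Col17a1 were not called, with highest adjusted p of 0.278, 0.309, 0.287 and 0.337. Lgi2 was not tested on log2 TPM or centred TPM. Centred TPM also ended the calls of Lrrc66 (0.167), Cntn1 (0.0566) and Col17a1 (0.0741), leaving out both wild-type mouse 1 and knockout mouse 3 that of Lrrc66 (0.064), and the mouse number as a block that of Sox14 (0.0575).

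**Figure D2:**
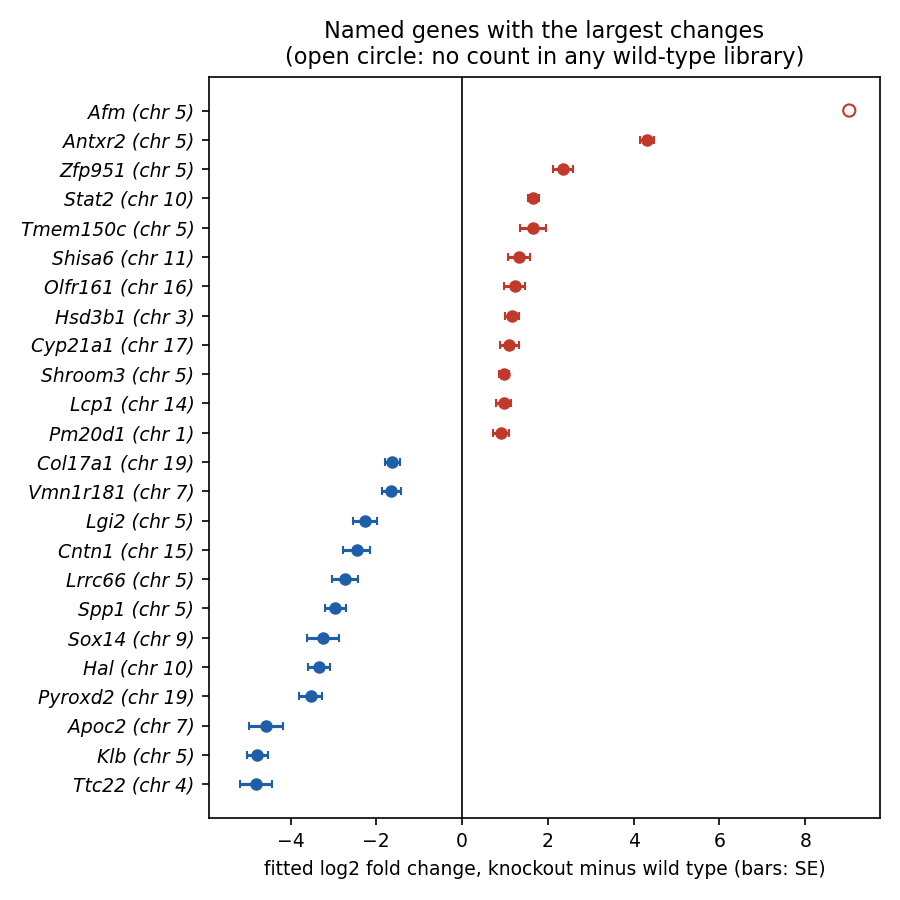
Fitted log2 fold changes, knockout minus wild type (x axis), of the 12 largest named rises (red) and 12 largest named falls (blue), with the chromosome of each gene (y axis). Bars are SEs of the fit. The open circle marks Afm, which had no count in any wild-type library, so that its fitted value is not a measured fold. The falls reach -4.81 (Ttc22) and the measured rises 4.32 (Antxr2).

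The called genes were unevenly spread over the chromosomes, a point noticed after their values were seen. In GENCODE M21, an annotation of the older GRCm38 build that was used only for chromosome names and gene order, 113 of the 119 called genes had a place. Chromosome 5, which carries Nsun7, held 30 of them, Nsun7 included, where 7.39 would follow from its 1301 tested genes (two-sided Fisher's exact test, adjusted p = 4.72e-10 over 21 chromosomes). Of these 30, 14 were higher and 16 lower in the knockout. Chromosome 12 held 16, against 4.25 from its size (adjusted p = 5.33e-05), and chromosome 2 held 1, against 8.71 (adjusted p = 0.0152). The test treats genes as independent, which neighbours need not be. Of the 24 named rises and falls, 9 lie on chromosome 5, namely Afm, Antxr2, Zfp951, Tmem150c, Shroom3, Klb, Spp1, Lrrc66 and Lgi2.

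**Figure D3:**
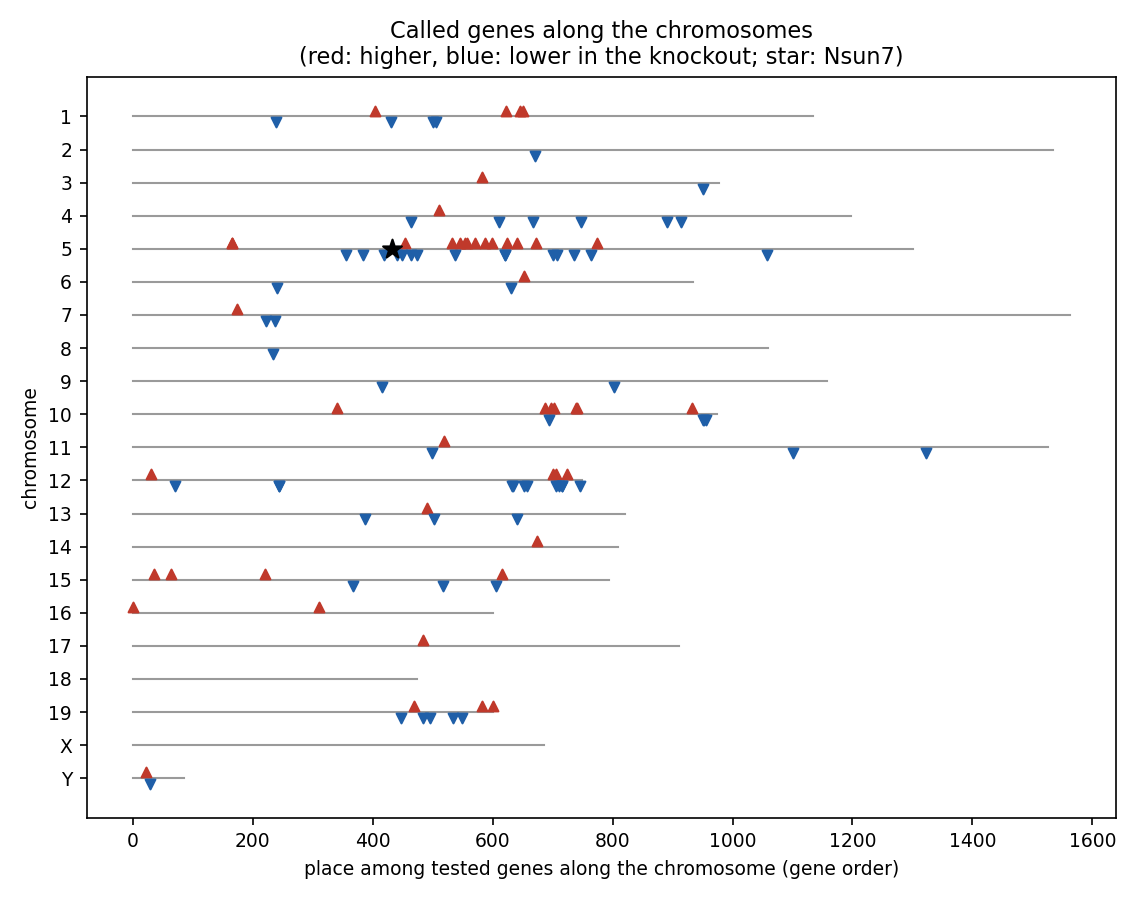
Called genes along each chromosome (y axis), by their place among the tested genes in the gene order of GENCODE M21 (x axis). Red triangles are higher and blue triangles lower in the knockout, grey lines span the tested genes, and the star marks Nsun7. Chromosome 5 holds 30 called genes, the most of any chromosome.

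The lists of sperm tail genes held no called gene. None of the 10 genes of the fibrous sheath, the structure that includes the longitudinal columns, passed the edgeR test (median log2 fold change 0.09, camera adjusted p = 0.779). Its members with the smallest p were Akap3, an anchoring protein of the sheath, at 302 ± 45.9 CPM in wild type and 399 ± 107 in the knockout (log2 fold change 0.40, adjusted p = 0.583), and Fsip2 (-0.25, adjusted p = 0.662). For the 14 genes of the outer dense fibres and the connecting piece 0 passed (camera adjusted p = 0.785), with Pmfbp1 at 0.31 (adjusted p = 0.65) and Spata6 at 0.25 (adjusted p = 0.656). Among 37 tested axoneme genes 0 passed (camera adjusted p = 0.832), and Rsph6a, a radial spoke protein, had the smallest p at -0.44 (adjusted p = 0.287), followed by Cfap206 at 0.26 (adjusted p = 0.665). Nor did any of 15 mitochondrial sheath genes pass (camera adjusted p = 0.478; Gykl1 0.32, adjusted p = 0.594, and Smcp -0.27, adjusted p = 0.607). For the annulus and septins the values were 0 of 7 (camera adjusted p = 0.702), with Septin2 at 0.28 (adjusted p = 0.625) and Slc26a8 at 0.17 (adjusted p = 0.681). For the manchette, the transient microtubule skirt of the elongating spermatid, they were 0 of 21 (camera adjusted p = 0.772), with Stk36 at -0.26 (adjusted p = 0.597) and Hook1 at 0.28 (adjusted p = 0.637). Adjusted over the list alone, no gene of these 6 lists passed either. Of their 104 different genes 3 had an unadjusted p under 0.05, and DESeq2 called 0. On the deposited TPM scale, where the median of all genes moved by 0.25, the values of Fsip2, Smcp and Stk36 turned positive.

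Other spermatid lists showed 1 called gene. Eno4, the enolase of the sperm tail, rose from 23.6 ± 2.98 to 41 ± 3.2 CPM (n = 3 per genotype; log2 fold change 0.79, SE 0.13, adjusted p = 0.0105), and was the sole member of 15 sperm glycolysis genes to pass, over all genes and adjusted over the list alone. Its call was lost without wild-type mouse 1 (adjusted p = 0.111), wild-type mouse 2 (0.112) or knockout mouse 2 (0.0618), on log2 TPM (0.105 and 0.119) or centred TPM (0.0754), and without both wild-type mouse 1 and knockout mouse 3 (0.0631), and Hspa12a overlaps it on the other strand. Pgk2, of the same list, was at 0.51 (adjusted p = 0.596; list, camera adjusted p = 0.523). None of the 15 chromatin condensation genes passed (median -0.18, camera adjusted p = 0.205), with the linker histone gene H1f6 at -0.44 (adjusted p = 0.461) and Prm3 at -0.53 (adjusted p = 0.479). None of the 27 acrosome genes passed (camera adjusted p = 0.785; Spaca1 0.33, adjusted p = 0.591, and Cylc1 -0.60, adjusted p = 0.631). Of 24 ion channel and signalling genes 0 passed (camera adjusted p = 0.794; Adcy10 0.48, adjusted p = 0.382, and Catspere1 -0.41, adjusted p = 0.449). Of 20 genes of ubiquitin pathways and cytoplasm removal 0 passed (camera adjusted p = 0.785; Alox15 -1.14, adjusted p = 0.39, and Marchf11 -0.38, adjusted p = 0.456).

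Germ cell stages did not differ past the threshold either. Elongating spermatid markers, 14 genes, had a median log2 fold change of -0.18 and a camera adjusted p of 0.125, with 0 members called. Prm3 and Tnp2, a transition protein gene at 1247 ± 151 CPM in wild type and 952 ± 181 in the knockout (SD, n = 3; log2 fold change -0.39, adjusted p = 0.542), had the smallest p. This list passed without wild-type mouse 2 (camera adjusted p = 0.0498) and without knockout mouse 2 (0.0148), and the chromatin condensation list passed without knockout mouse 2 (0.0426). None of the 13 round spermatid markers passed (camera adjusted p = 0.785; Spaca1 as above and Izumo1 0.19, adjusted p = 0.694), nor any of the 12 pachytene markers (0.559; H1f6 as above and Piwil1 -0.21, adjusted p = 0.656). The 12 leptotene and zygotene markers had a median of -0.13 and 0 called members (camera adjusted p = 0.0828; Meiosin -0.34, adjusted p = 0.467, and Dmc1 -0.36, adjusted p = 0.562), and passed as a list without wild-type mouse 3 (camera adjusted p = 0.0458). The 12 spermatogonial markers had 0 called members (camera adjusted p = 0.718), with Stra8 at -0.46 (adjusted p = 0.325) and Gfra1 at 0.52 (adjusted p = 0.404). Of 27 germ granule and piRNA genes 0 passed (camera adjusted p = 0.832; Tdrkh 0.27, adjusted p = 0.631, and Piwil1). On the TPM scale the value of Piwil1 turned positive.

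Markers of Leydig cells, the testosterone-producing cells between the tubules, were higher as a group in the knockout. The median log2 fold change of the 10 markers was 0.58 and 8 were above 0 (camera adjusted p = 0.00896 with a preset correlation, and adjusted p = 0.903 with an estimated correlation). Over all genes 2 members passed, Hsd3b1 and Hsd17b3, which makes testosterone (18.9 ± 2.89 to 33 ± 2.82 CPM, n = 3 per genotype; log2 fold change 0.80, SE 0.14, adjusted p = 0.0182). Adjusted over the list alone 3 passed, the third being the luteinizing hormone receptor Lhcgr (0.92). Insl3, the most abundant member, was at 1608 ± 541 CPM in wild type and 2213 ± 955 in the knockout (log2 fold change 0.46, adjusted p = 0.728). The median over the members, centred on the 6 libraries, was 0.82, 0.12 and -0.14 in knockout mice 1, 2 and 3 and -0.23, -0.20 and -0.44 in wild-type mice 1, 2 and 3. In knockout mice 1, 2 and 3 macrophage markers stood at 0.591, 0.051 and -0.352 and fibroblast markers at 0.288, 0.1 and -0.341, also highest in mouse 1 and lowest in mouse 3. Without knockout mouse 1 the list no longer passed (camera adjusted p = 0.146, median 0.20), while Hsd3b1 (1.09, adjusted p = 0.00248) and Hsd17b3 (0.77, adjusted p = 0.0117) did. Hsd17b3 lost its call without wild-type mouse 1 (adjusted p = 0.143), wild-type mouse 2 (0.0853) or knockout mouse 2 (0.0928), and on log2 TPM (0.0589 and 0.0734).

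Of the other somatic cell lists 1 passed the camera test. The 9 markers of peritubular myoid and smooth muscle cells all had values below 0 and were lower as a group (median -0.25, camera adjusted p = 0.0155 with a preset correlation, and adjusted p = 0.903 with an estimated correlation), with no member past the test. Des was at -0.39 (adjusted p = 0.485) and Tagln at -0.35 (adjusted p = 0.512). The group's call was lost without wild-type mouse 1 (camera adjusted p = 0.0567), knockout mouse 3 (0.0779) or both (0.315, median -0.12). Centred on the 6 libraries, these markers were lowest in knockout mouse 3 (-0.307), as were Sertoli markers (-0.355) and fibroblast markers (-0.341). All 11 macrophage markers had values above 0 (median 0.24, camera adjusted p = 0.125, 0 called), with Mrc1 at 0.24 (adjusted p = 0.637) and Cd163 at 0.63 (adjusted p = 0.641). The macrophage list passed without wild-type mouse 2 (camera adjusted p = 0.0123), without knockout mouse 3 (0.00113) and without both wild-type mouse 1 and knockout mouse 3 (0.00908). None of 15 Sertoli cell markers passed (camera adjusted p = 0.478; Dhh -0.21, adjusted p = 0.663, and Clu -0.20, adjusted p = 0.716, both positive on the TPM scale). The Sertoli list passed as lower without knockout mouse 1 (camera adjusted p = 0.028), and its direction turned without knockout mouse 3 (0.784). Of 8 endothelial markers 0 passed (camera adjusted p = 0.884; Kdr 0.39, adjusted p = 0.613, and Egfl7 -0.29, adjusted p = 0.63). Of 8 fibroblast and capsule markers 0 passed over all genes (camera adjusted p = 0.785) and 1 passed adjusted over the list alone, Pdgfra (0.55, adjusted p = 0.135 over all genes), while Dcn was at 0.21 (adjusted p = 0.76) and at -0.05 without knockout mouse 1. Both Pdgfra and Kdr lie on chromosome 5, where called genes gathered, so their values may reflect place rather than cell type. Just 4 blood cell markers and 2 epididymal markers were high enough to test, with 0 called in each (camera adjusted p = 0.785 and 0.702; Cd3e -0.77, adjusted p = 0.443, Slc4a1 0.60, adjusted p = 0.676, Rnase10 0.40, adjusted p = 0.626, and Cst8 -0.05, adjusted p = 0.923).

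The lists of cytosolic ribosome and respiratory chain genes were slightly lower as groups, with no list member called. Rps26, a ribosomal protein gene outside the list and named after its values were seen, was called (log2 fold change -0.97). In the GENCODE M21 gene order it lies at place 950 of chromosome 10, near the called genes Suox (952) and Pmel (955). Its called transcript was at -5.03 (edgeR quasi-likelihood test, adjusted p = 0.00367). Its call is therefore not read as part of the fall of the list. The 30 ribosomal protein genes had a median log2 fold change of -0.18, and 23 were below 0 (camera adjusted p = 0.0171 with a preset correlation, and adjusted p = 0.903 with an estimated correlation). Rpl19 was at 186 ± 24.3 CPM in wild type and 145 ± 20.4 in the knockout (log2 fold change -0.36, adjusted p = 0.511) and Rpl3 at -0.30 (adjusted p = 0.515). The 23 nuclear respiratory chain genes had a median of -0.11, with 22 below 0 (camera adjusted p = 0.0351 with a preset correlation, and adjusted p = 0.903 with an estimated correlation; Cox5b -0.45, adjusted p = 0.39, and Ndufb8 -0.36, adjusted p = 0.596). Both groups moved with single libraries: without wild-type mouse 1 the camera adjusted p was 0.21 for each, and without knockout mouse 3 it was 0.485 and 0.842. The respiratory chain list also lost its call without wild-type mouse 2 (0.062). Centred on the 6 libraries, ribosomal protein genes stood highest in wild-type mouse 1 (0.203) and lowest in knockout mouse 3 (-0.348). The nuclear RNA Malat1, picked after its values were seen, took its smallest share of the counts in wild-type mouse 1 (0.0987%) and its largest in knockout mouse 3 (0.2%). Its share lay between 0.0987% and 0.115% in wild type and between 0.135% and 0.2% in the knockout, without overlap, and it was not called (log2 fold change 0.52, adjusted p = 0.217). The 13 mitochondrially encoded mRNAs had a median of 0.33 and 0 called members (camera adjusted p = 0.396; mt-Nd4 0.46, adjusted p = 0.655, and mt-Nd5 0.37, adjusted p = 0.659). This list passed as higher without wild-type mouse 3 (camera adjusted p = 0.02) and without knockout mouse 1 (0.00352), and turned without both wild-type mouse 1 and knockout mouse 3 (0.635).

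The remaining lists stayed short of the threshold. The 9 enzymes and readers of RNA 5-methylcytosine, relatives of Nsun7 among them, had 0 called members (median 0.11, camera adjusted p = 0.785), with Nsun3 at 0.26 (adjusted p = 0.65) and Nsun2 at 0.22 (adjusted p = 0.671). Of 26 mRNA decay genes 0 passed (camera adjusted p = 0.785; Pan3 0.27, adjusted p = 0.641, and Upf1 -0.22, adjusted p = 0.65, which was positive on the TPM scale). Of 17 germ cell chaperones 0 passed (0.785; Tcp1 0.25, adjusted p = 0.664, and Dnajc5b 0.46, adjusted p = 0.67). None of the 11 tested interferon response genes passed, a list that does not hold Stat2 (1 had an unadjusted p under 0.05; camera adjusted p = 0.791; Oasl2 0.36, adjusted p = 0.548, and Usp18 -0.22, adjusted p = 0.765). Of 12 p53 and apoptosis genes 0 passed (0.652; Trp53inp1 0.41, adjusted p = 0.465, and Eda2r 0.72, adjusted p = 0.572). Of 11 immediate early and heat shock genes 0 passed (0.523; Junb -0.38, adjusted p = 0.456, and Ier2 -0.33, adjusted p = 0.602). Over the 485 different genes of all lists 3 passed, 37 had an unadjusted p under 0.05, and DESeq2 called 4, the fourth being Lhcgr. In all, 4 of the 34 lists passed camera with a preset correlation of 0.01. That number did not set the genotypes apart from other splits of the 6 libraries into 3 and 3. Of 10 splits 6, the real one among them, gave at least 4 lists, and the highest gave 8. None passed with an estimated correlation, or by fry's test of one direction, where the smallest adjusted p was 0.903 and 0.805, and none had an unadjusted p under 0.05 in either. For the outer dense fibre, axoneme, ion channel and blood cell lists the median, the mean and the direction of the camera test did not all have the same sign.

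**Figure D4:**
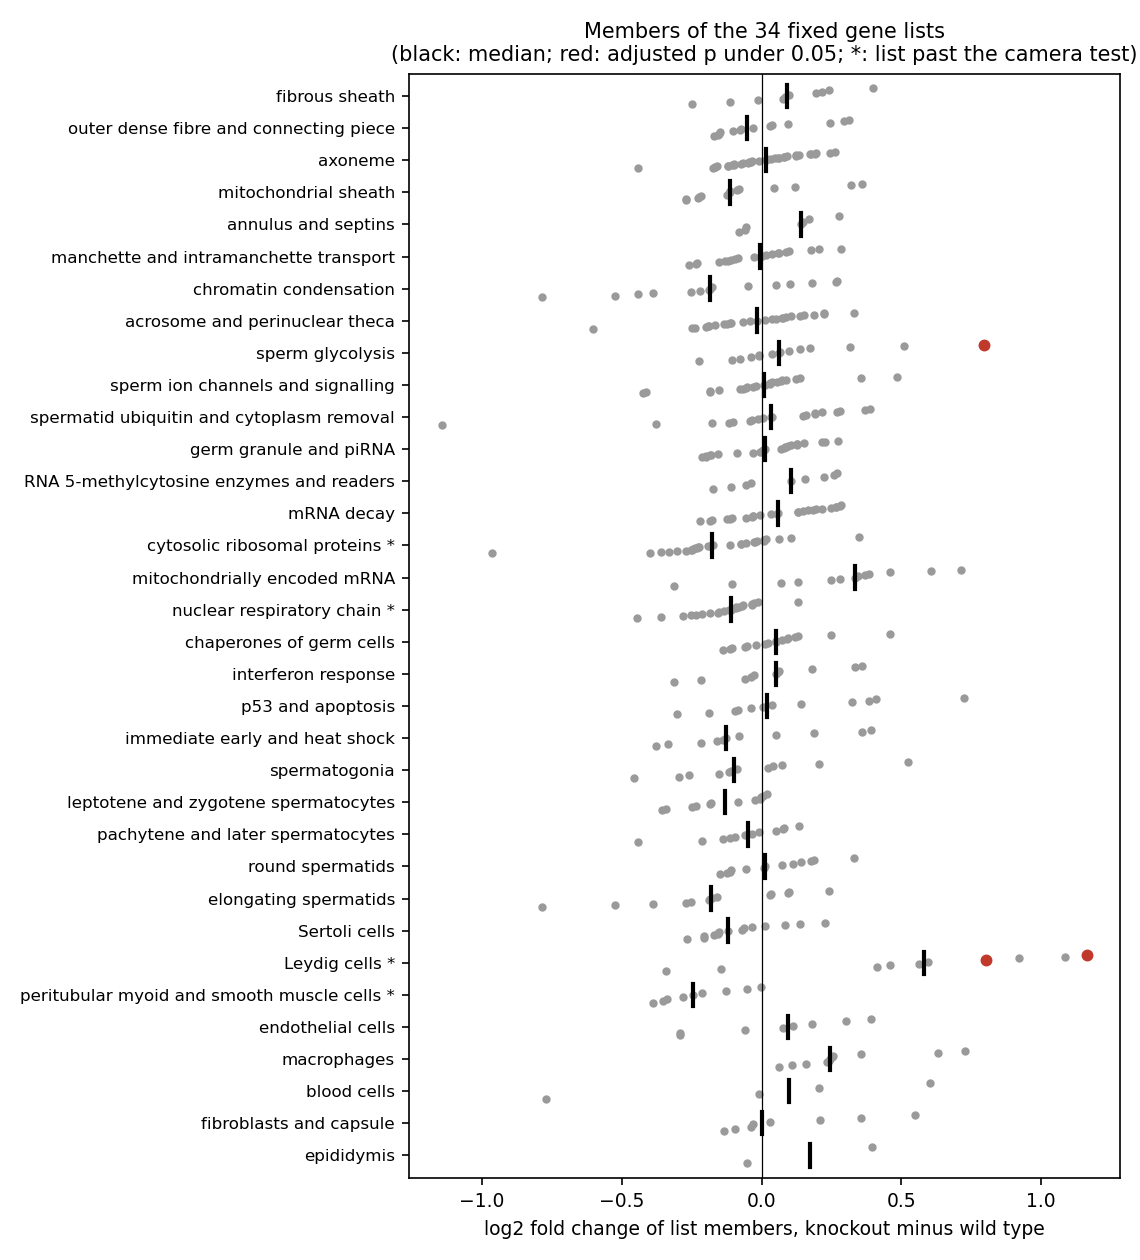
Log2 fold change, knockout minus wild type (x axis), of each tested member of the 34 gene lists (y axis). Grey points are members that did not pass, red points those with an adjusted p under 0.05, black bars the list medians, and asterisks the 4 lists past the camera test with a preset correlation. The Leydig cell list has the highest median, 0.58.

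With edgeR single transcripts gave fewer calls than genes, and with DESeq2 they gave more (416 against 203). Of 58773 transcripts tested, 16 passed, 7 higher and 9 lower in the knockout, and they belonged to 14 genes (edgeR quasi-likelihood test; 2800 at an unadjusted p under 0.05). Of those genes 7 were also called at the gene level, among them Antxr2 with 2 transcripts, Klb (log2 fold change -4.93) and Stat2 (1.75). The other 7, named after their values were seen, were tested as genes and not called: Btnl10, Tmem63c, Tex22, Tpst2, Klc1, Rint1 and Myh11. The transcript estimates carry an uncertainty from reads shared between isoforms that the test did not include. Leaving out 1 library left between 0 and 6 called transcripts, with 0 without wild-type mouse 2, wild-type mouse 3 or knockout mouse 2. With the mouse number as a block 0 transcripts passed, and with voom 10.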

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

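The settings with the length trend removed, without Rmrp, Ccnb1ip1 and Lars2, without both wild-type mouse 1 and knockout mouse 3, and on centred TPM were chosen after seeing the data. The count of 119 called genes became 180 with no low-count filter, 331 with the replicate number as a block, 203 with DESeq2, 286 with voom and sample weights, 52 and 48 on log2 TPM with a pseudocount of 1 and 0.1, and 57 on centred TPM. Leaving out 1 library gave between 67 and 166. On TPM the median of all genes moved by 0.25 and 0.30 and 63.5% and 62.5% of the calls were higher, against 41.2% in the report and 29.8% after centring. The labels do not state that the mouse numbers pair the libraries. Deviations from the genotype mean correlated between mice of the same number at 0.177, -0.00476 and 0.199 for numbers 1, 2 and 3. Other pairs reached at most 0.0565, so an effect shared by the number stays open. The 16 transcripts became 0 with the block (3740 at an unadjusted p under 0.05), 416 with DESeq2, 10 with voom, 2 without wild-type mouse 1 and knockout mouse 3, and between 0 and 6 without 1 library. The log2 fold change of Nsun7 was -0.46 and -0.50 on TPM (adjusted p = 0.406 and 0.407), -0.75 on centred TPM (adjusted p = 0.118), and between -1.03 and -0.76 without 1 library, where the calls lost were those the report names. The 4 called lists became 1 on TPM with either pseudocount and 1 on centred TPM (the Leydig list each time), 0 with an estimated correlation, 0 with fry, 2 with the length trend removed, 2 without wild-type mouse 1 and knockout mouse 3, and between 1 and 6 without 1 library. Apart from the fits on fewer libraries, the cause was not tested.

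On log2 TPM with a pseudocount of 1 and 0.1 these uncalled genes turned positive: Fsip2 (0.053 and 0.064), Smcp (0.076 and 0.077), Stk36 (0.17 and 0.18), Piwil1 (0.12 and 0.12), Upf1 (0.091 and 0.091), Usp18 (0.040 and 0.066), Dhh (0.021 and 0.022), Clu (0.078 and 0.078) and Cst8 (0.28 and 0.28). On centred TPM, where the median of all genes was at -0.038, none of these genes was positive, so their turn went with the shift of all genes. Nsun3 was at -0.16 on centred TPM and Slc4a1 at -0.018 with voom. Dcn ranged from -0.049 to 0.39 and Cst8 from -0.13 to 0.0083 when 1 library was left out, with the change of sign without knockout mouse 1 and without wild-type mouse 3. Without both wild-type mouse 1 and knockout mouse 3, Cfap206 was at -0.025, Dnajc5b at -0.037 and Slc4a1 at -0.11; without 1 library they ranged from 0.023 to 0.397, from 0.15 to 0.763 and from 0.00036 to 0.882. In that fit the ribosomal, respiratory chain and fibrous sheath lists also changed direction, with a camera adjusted p of 0.994 each, as did the mitochondrially encoded and Sertoli lists (0.635 each). Leaving out 1 library gave camera adjusted p from 0.00352 to 0.485 for the ribosomal list, from 0.000584 to 0.842 for the respiratory chain, from 6.29e-05 to 0.146 for the Leydig list from 0.00609 to 0.0779 for the peritubular list and from 0.453 to 0.975 for the fibrous sheath, as well as from 0.00352 to 0.975 for the mitochondrially encoded list and from 0.028 to 0.784 for the Sertoli list, which turned without knockout mouse 3. Of the 26 called genes that the report names beside Nsun7, all 26 kept their call and direction with RLE or upper quartile scaling, no filter, a mean CPM of at least 1, DESeq2, voom and gene sums. The block kept 25, losing Sox14 (adjusted p = 0.0575). TPM kept 13 of 25 with either pseudocount, and centred TPM 15 of 25. Of the 26, 25 were kept with the length trend removed and 20 without both wild-type mouse 1 and knockout mouse 3. Leaving out 1 library kept between 18 and 24. Pgk2, Catspere1 and Pdgfra, not called in the report, passed in at least 1 of the block and voom fits. Apart from the genes that turned positive on log2 TPM, the cause of each of these changes was not tested.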

Other observations

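The tests of shared reads, of gathering over all chromosomes against other splits, and of the numbers of calls against other splits were written before their results were seen. The tests on chromosome 5, on the other chromosomes, on the Leydig markers and on the ribosomal list were chosen after the results were seen.

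Stretches of chromosomes 5 and 12 held many of the genes that changed. On each, 11 of 100 neighbouring tested genes were called, where 0.568 would follow from all tested genes, and the most on any other chromosome was 6, on chromosome 10. The stretch of chromosome 5 ran from Afm to Zfp951, at places 533 to 624 among its tested genes, with Nsun7 outside it at place 432. That of chromosome 12 included Meg3, an imprinted long noncoding RNA, and Siva1, a gene of apoptosis signalling. These stretches and their genes were picked after their values were seen. The unnamed transcript gene 4930465M20Rik, in the stretch of chromosome 12, had no count in any knockout library and was at least 30.5-fold lower there, and Gm28955 was at least 8.98-fold lower, both against 3 counts per library. Lars2 took 0.513% of the counts in wild-type mouse 1 and between 0.0278% and 0.0806% in the other libraries.

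Called genes lay close together, with 50 of 113 within 10 tested genes of another (10000 random draws, median 12 and highest 31, permutation p = 0.0001, the smallest these draws can give), and 30 lay on chromosome 5. Random draws take genes as independent, so this p and the others from such draws do not allow for neighbours that vary together. Reads shared between neighbours within 100 kb were argued against as the whole source. After keeping 1 call of each run within 100 kb, 40 of 106 still lay near another (highest draw 27). Reads shared over longer distances were not tested. For neighbours varying together in any grouping, as many genes of smallest p in the other splits gave at most 31 near another and 12 on chromosome 5. None reached the real 50 and 30, but 10 splits are too few for a share under 0.05. These other splits also held at most 12 called genes, so the explanation is not excluded. DNA of another strain around Nsun7, carried over from the making of the allele, may account for the gathering on chromosome 5: within 200 tested genes on each side of Nsun7 19 of 400 were called against 10 of 900 on the rest of the chromosome (Fisher's exact test, p = 0.000122), with p = 0.00492, 0.0716 and 1.94e-05 for 50, 100 and 400 genes on each side. Off chromosome 5, 30 of 83 lay near another call, where random draws gave a median of 6 and at most 23 (permutation p = 0.0001). After keeping 1 call of each run 22 of 77 did (highest draw 20). Other splits gave at most 22 near another, short of the margin of 10 genes asked for, which is too close to part the explanations. Over all chromosomes, genes called by a transcript alone lay near a call in 3 of 7 cases (permutation p = 0.0853). Of these genes Tpst2 and Rint1 lie on chromosome 5, so the value is not one for the other chromosomes alone. Segments on several chromosomes stay open. Loss of Nsun7 as the source of changes in single genes stays open as well and was not tested apart from position.

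Leydig cell markers were higher in the knockout with a preset correlation (median log2 fold change 0.58, adjusted p = 0.00896), and not past the threshold with an estimated one (adjusted p = 0.903 with an estimated correlation, 0.805 by fry). Endothelial and fibroblast markers had a median of 0.05, below that of the Leydig markers (difference 0.53, permutation over genes, p = 0.00285). That p takes genes of 1 list as independent. The estimated correlations were 0.561 in the Leydig list, 0.483 in the endothelial list and 0.71 in the fibroblast list. Fibroblast markers were also highest in knockout mouse 1. The test therefore cannot settle whether every kind of interstitial tissue rose alike. More tissue holding Leydig cells together with macrophages stays open: macrophage markers had a median of 0.24, with 11 of 11 above 0, and were not told apart from the Leydig markers (difference 0.34, permutation over genes, p = 0.0909). Knockout mouse 1 alone could not be told apart from the genotype: without it the median was 0.20 (SD over markers 0.465), and the list's adjusted p was 0.146; the call was lost, for a cause that was not tested. A change in the number or the activity of Leydig cells in the knockout may also stand behind it and was not tested.

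The ribosomal protein list (median -0.18, SD over genes 0.222, adjusted p = 0.0171) and the respiratory chain list (median -0.11, SD 0.124, adjusted p = 0.0351) were lower with a preset correlation, and neither passed with an estimated one (adjusted p = 0.903 with an estimated correlation, 0.805 by fry). A length trend between libraries stays open for the ribosomal list: with the trend removed its median was -0.14 (SD 0.225) and its adjusted p 0.114, so the call ended with most of the fold left. The respiratory chain list also lost its call (adjusted p = 0.114), while its median was -0.12 (SD 0.113), no smaller than before. Wild-type mouse 1 and knockout mouse 3 lay at the ends of the first principal component. Without them the ribosomal median was -0.0051 (SD 0.149) and the respiratory chain median 0.0048 (SD 0.085), with an adjusted p of 0.994 each. In both lists wild-type mouse 1 stood highest of the wild types and knockout mouse 3 lowest of all libraries. Leaving out both pulls the medians towards 0 in any case, so this fit cannot tell whether the fall rests on these 2 libraries. An effect of the genotype was not tested apart from them.

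The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 119 genes and the highest other 12, and 1 split of the 10, the real one, gave as many. For transcripts the values were 16 and 1, again with 1 split. For gene lists the real split gave 4 and the highest other 8, and 6 of the 10 splits gave at least as many. The number of called lists was therefore no higher than other groupings of the same libraries gave, the Leydig, peritubular, ribosomal and respiratory chain calls included.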
